A study of Deinococcus radiodurans with 3 samples.

How the data were processed

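Genomic DNA of *Deinococcus radiodurans* R1 was measured in 3 libraries that form 1 group, named by the replicate numbers of the labels. Per the labels' protocols, 100 ng of DNA was sheared, ligated to adaptors, denatured and deaminated with 6 μM A3A for 2 h at 37 °C, then amplified in 10 and 5 cycles of PCR and sequenced. Per the submitters' processing notes, FastQC 0.11.8, Trim Galore 0.6.7, cutadapt 3.5, Bismark 0.23.1 and SAMtools 1.9 were used; their settings, the genome build and any removal of duplicate reads are not given in the sources used here. PCR copies are not independent molecules, so intervals and tests on reads cover counting error only. Reads that map poorly, or stretches that amplify poorly, would lower the depth or shift the level at the cytosines concerned.

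The deposited files give, per the file headers, 2 counts for each cytosine, the reads that kept the C call and the converted reads. They also give the deposited fraction, which equals the first count divided by the sum of both. Levels were computed from the counts and are printed in percent. Cytosines with fewer than 10 reads in any library were left out, which kept 2115527 of 2188398. The median depths of 373, 269 and 708 reads set the precision at single sites.

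No genome was used. The files list each cytosine of both strands, so C and G were placed from their positions and every other base was treated as A or T (W). CCGCGG holds no A or T and could be placed exactly. In inverted repeats, W opposite W counted as a possible pair, so a perfect repeat is one without a mismatch in C, G and W. The search designed over all hexamers was therefore run over 1458 classes of C, G and W, the near-motif hexamers became 10 classes, and the preceding bases A and T were not separated. Coordinates are those of the files and are counted from 1.

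The tests, the coverage minimum, the thresholds and the alternatives were chosen before the data were examined, except where stated. Motif levels were set against 10000 random sets of CCG cytosines, and differences between classes of sites were tested with 100000 permutations. Read counts were compared with Fisher's exact test, and intermediate sites with a one-sided binomial test against each library's background outside the hexamer. P-values were adjusted by the Benjamini-Hochberg method. Hexamer counts were compared with a first-order Markov model, a comparison added after the data were examined. Further analyses were not in the plan. These were the test of hexamer density between replicons, the correlation between strands and the split of strand differences by preceding base. The pairwise tests of flanking bases and the range between libraries by depth were not in it either. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The named sites follow a fixed rule: the 10 motif cytosines with the lowest mean, the 10 high-level sites outside the motif and the 10 intermediate sites with the highest means, and the 3 motif cytosines with the widest range between libraries. The hexamer with the widest strand difference was named after its value was seen.

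The procedures were tested on simulated counts drawn at the real depths. Of 100 cytosines planted at 70% and 100 planted at 20%, 100% were called high-level and intermediate, and 0 of 2114694 background cytosines were called. Strand differences of 30 points were called at 99.0% of 96 hexamers, and 0% of 220 hexamers with equal strands were called. The simulated background was the same at all cytosines, so it does not cover sites that resist deamination. The simulated reads were independent, so the rates of strand calls do not cover PCR copies. Calling rates were not measured at levels near the thresholds of 10% and 50%. They were not measured for strand differences smaller than 30 points either, while the median difference in the data was 12.0 points. The rates therefore do not give the sensitivity for such sites and hexamers.

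The designed comparisons of genes with intergenic sequence and of gene lists, and the named genes, were not run. Of the 3124 coding models in the gene table at hand, 51 (1.63%) began and ended with start and stop patterns at their coordinates in the sequence used here. The coordinates of the gene table therefore do not match this sequence, for a reason that was not tested, and no gene is named. The tests of explanations in the closing part were mostly chosen after the patterns were seen.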

Results

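N4-methylcytosine was mapped at single-base resolution in genomic DNA of *Deinococcus radiodurans* strain R1, a bacterium known for its resistance to ionising radiation and desiccation. Cells had been cultured for 12 h, and the sheared, denatured DNA was treated with A3A (APOBEC3A), an enzyme that deaminates unmodified cytosine so that it is sequenced as T. A cytosine that carries a methyl group on its N4 atom is largely spared and keeps its C call. The share of reads with a C call at a cytosine is called its level here. There was 1 group with 3 libraries, and the files listed the same 2188398 cytosines of both strands in each of them. The libraries held 927841403, 633863663 and 1689813322 base calls at these cytosines, and their median depths were 373, 269 and 708 reads. In all 3 libraries, 2115527 cytosines (96.7%) had at least 10 reads, and the values below refer to these. The labels do not say that the libraries came from separate cultures, so no p-value is taken to measure the spread between cultures. Tests over libraries or sites measure only the spread between these libraries or between sites within 1 genome. Tests on reads cover counting error only.

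Almost all cytosines of the genome lost their C call. The mean level over the covered cytosines was 0.584% ± 0.191 (SD, n = 3 libraries), with 0.764%, 0.604% and 0.383% in libraries 1, 2 and 3. The median cytosine had a level of 0.405%. Outside the hexamer CCGCGG, the pooled share of C calls, which measures the background of the assay, was 0.613%, 0.536% and 0.312%. The background thus differed between the libraries and was lowest in library 3, the most deeply sequenced one.

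The second cytosine of CCGCGG, the hexamer known as the target of a cytosine N4-methyltransferase in this species, kept its C call in most reads. The files hold 337 copies of the hexamer and thus 674 such cytosines, of which 633 were covered in all libraries and 41 were not. Their mean level was 69.9% ± 1.18 (SD, n = 3 libraries), with 68.6%, 70.7% and 70.5% in the single libraries. The median site had a level of 74.3%, the interquartile range was 59.4% to 80.6%, and the range was 29.3% to 94.5%. A mean level of at least 10% was reached at 633 of the 633 sites. At the 223088 covered cytosines that also stand between C and G but lie outside the hexamer, the mean level was 0.525% ± 0.181. The difference was 69.4 ± 1.32 percentage points (SD, n = 3 libraries). None of 10000 random sets of 633 such cytosines reached the motif's median, as the highest set median was 0.447% (permutation by random sets, one-sided p = 0.0001, the smallest that this number of sets can give). The difference was positive in 3 of 3 libraries, for which an exact sign-flip permutation test gives a two-sided p of 0.25, the smallest possible with 3 libraries.

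The high levels were found at 1 place of the hexamer. Its first cytosine had a mean level of 0.778% ± 0.188 and the cytosine at its place 4 was at 0.574% ± 0.195 (SD, n = 3 libraries, 633 sites each), values close to the background. Within the same copy and strand, the second cytosine was 69.1 percentage points above the first and 69.3 points above the one at place 4. It was the higher one in 633 of 633 cases in both comparisons (sign-flip permutation test over sites, two-sided, p = 1e-05 each, the smallest that the resamples can give).

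**Figure D1:**
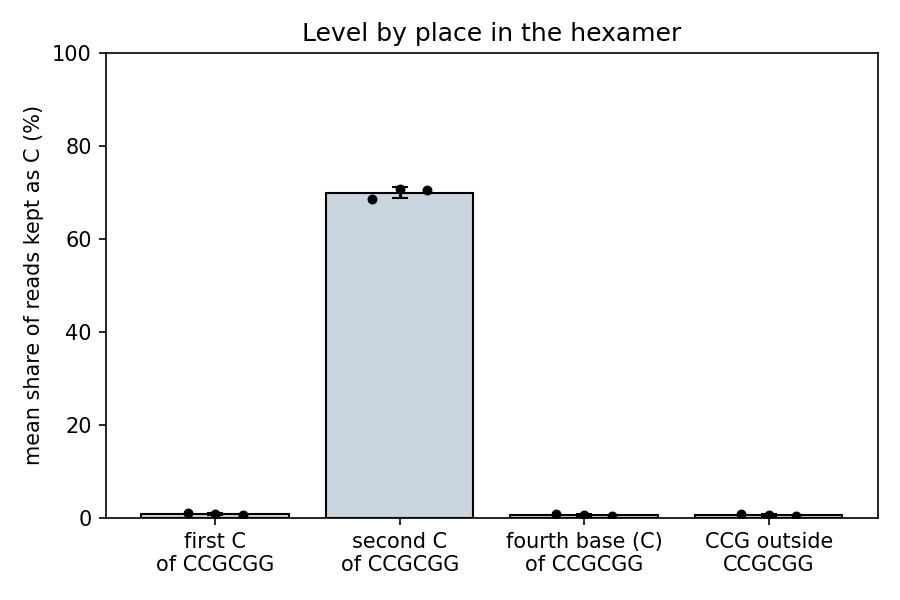
Mean level (share of reads kept as C, in percent) at the 3 cytosines of CCGCGG and at CCG cytosines outside the hexamer. Bars are the means of 3 libraries, error bars the SD and points the single libraries. The second cytosine stands at 69.9%, and the other classes lie below 1%.

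Cytosines with a high level, defined as at least 50% in each of the 3 libraries, numbered 604. Of these, 558 (92.4%, exact 95% confidence interval 89.97 to 94.37%, counting error only) were the second cytosine of CCGCGG and 46 lay outside the hexamer. The 46 lay in 5 clusters of neighbouring sites, with 25 in the largest group of them. The interval treats sites as independent, so it is too narrow for sites that come in clusters. In the other direction, 558 of the 633 covered motif cytosines (88.2%) were at a high level, against 1 of the 223088 CCG cytosines outside the hexamer (Fisher's exact test, two-sided, with a p too small to be held as a floating point number). The number outside the hexamer can only rise when a library is left out, as fewer libraries must then pass. It was 92 without library 1 and 175 without library 3, against 57 without library 2. The share of the motif fell to 86.3% and 76.2% without libraries 1 and 3. With sites passing in at least 2 of the libraries, the share was 71.7%. The count of 604 was 929 at a level of at least 30% and 344 at 70%. When cytosines in perfect inverted repeats with at least 6 C:G pairs were left out, an alternative chosen after seeing the data, 487 high-level sites were left and 0 of them lay outside the hexamer. This filter also removed motif cytosines, whose high-level sites fell from 558 to 487. The 10 high-level sites outside the hexamer with the highest means lay next to each other on chromosome 1, between positions 807854 and 807878, at means of 84.7% to 91.8%. They belong to a cluster of 26 sites, 26 of which lie in an inverted repeat with up to 15 C:G pairs. The highest, at position 807859 on the minus strand, had a level of 91.8% ± 5.01 (SD, n = 3 libraries) at depths of 31 to 83 reads.

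A further 1987 cytosines were at an intermediate level, with a mean of at least 10% and a binomial test against the library's background passing an adjusted p of 0.01 in all 3 libraries. Only 74 of them were motif cytosines, 5 were other cytosines of the hexamer and 1908 lay outside it. A single covered motif cytosine was in neither class. The count of 1987 was 1010 without cytosines in inverted repeats, 5950 on pooled reads, and 3621 and 852 with a mean of at least 5% and 20%. The 10 intermediate sites with the highest means ranged from 60.3% to 65.3%. Of these, 2 were motif cytosines, and the highest of all was the motif cytosine at position 86447 of the minus strand of chromosome 2, with 65.3% ± 16.8 (SD, n = 3 libraries) at 10 to 29 reads. A group of 5 lay between positions 397754 and 397782 of chromosome 1, and 3 lay between positions 89314 and 89328 of plasmid pMP1, where the depth was 11 to 31 reads.

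An open search over hexamers returned the same motif. The files list every cytosine of both strands, so that C and G are known at every position and the remaining positions are A or T, written W here. Among the 1458 hexamer classes over C, G and W that contain a cytosine at a stated place, CCGCGG with the cytosine at its second place had the highest share of high-level sites, 558 of 633. Of the other classes with a cytosine at the second place, WCCCCW had the highest share, 5 of 4904 cytosines, which did not pass Fisher's exact test (adjusted p = 0.261). In all, 66 classes passed an adjusted p of 0.05, a number that includes classes that overlap the motif shifted along it.

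Hexamers that differ from CCGCGG by 1 base, with the second cytosine kept, were all within 0.180 percentage points of the background. Of the 10 such classes, 5 were above and 1 was below the cytosines of the same trinucleotide (permutation over cytosines, Benjamini-Hochberg adjusted). The widest difference was that of CCGCWG, with a level of 0.706% ± 0.188 against 0.525% (SD, n = 3 libraries, adjusted p = 0.00025 by the permutation). Only 1 cytosine in these classes was at a high level.

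The level at the motif differed with the base just 5' of the hexamer on the same strand. It was 80.2% ± 1.45 after G (330 sites), 61.4% ± 1.09 after A or T (164 sites) and 55.5% ± 0.743 after C (139 sites; SD over n = 3 libraries). These classes accounted for 71.4% of the variance between sites (permutation of the between-class sum of squares, p = 1e-05, the smallest possible). G exceeded C by 24.7 ± 0.876 points and A or T by 18.7 ± 0.363 points, and A or T exceeded C by 5.91 ± 0.578 points (adjusted permutation p = 2e-05 each). A high level was reached by 329 of the 330 sites after G, by 134 of 164 after A or T and by 95 of 139 after C. The base just 3' of the hexamer showed no detectable difference, with 69.6% for C, 69.7% for G and 70.6% for A or T (permutation p = 0.709). Among the 10 motif sites with the lowest means, 4 followed A or T and 6 followed C. The lowest was at position 198230 on the minus strand of chromosome 2, with 29.3% ± 1.02 (SD, n = 3 libraries) at 501 to 1406 reads, in the sequence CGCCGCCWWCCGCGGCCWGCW. The next was at position 2283015 on the plus strand of chromosome 1, with 29.8% ± 1.34 at 143 to 425 reads.

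**Figure D2:**
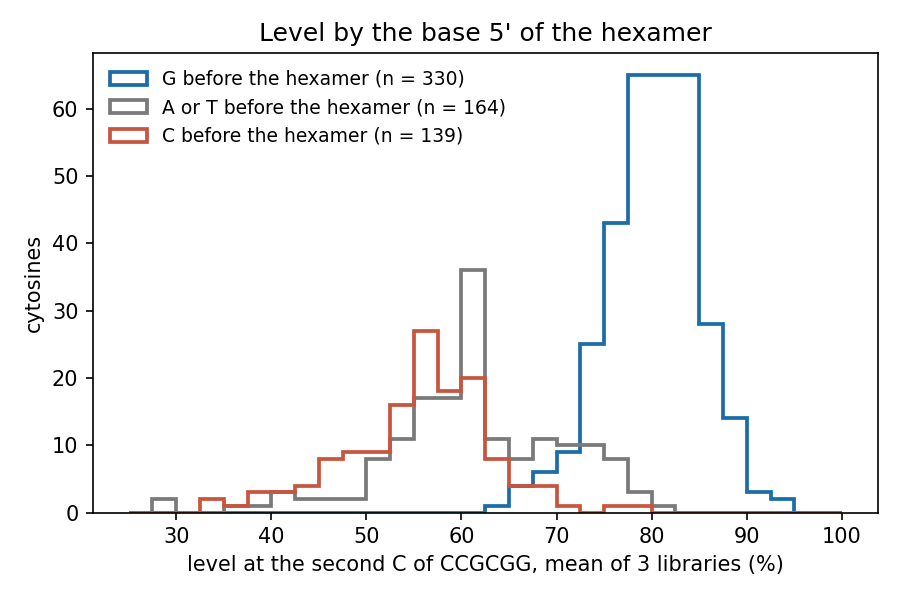
Number of motif cytosines (vertical axis) by level at the second C of CCGCGG, mean of 3 libraries in percent (horizontal axis), for 330 sites after G, 164 after A or T and 139 after C. Sites after G lie around 80.2%, and the others around 61.4% and 55.5%.

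CCGCGG reads the same on both strands, and the second cytosines of the strands often differed in level. Of 316 hexamers covered on both strands, 165 (52.2%) had a higher level on the same strand in all 3 libraries (Fisher's exact test within each library, adjusted p under 0.05). With the reads of the libraries pooled, the number was 251. Both strands were at a high level in 250 hexamers, 1 strand in 58 and neither in 8. The median absolute difference was 12.0 percentage points. Across hexamers, which are not independent replicates, the levels of the strands were not correlated (Pearson's r = -0.011, permutation p = 0.843, and Spearman's rho = -0.016, permutation p = 0.777). Differences were most frequent where G preceded the hexamer on one strand only: 72 of 78 hexamers with G and C differed, and 60 of 90 with G and A or T. With the other combinations, 16 of 81 differed with G before both strands, 5 of 16 with C before both, 8 of 23 with A or T before both, and 4 of 28 with C before one and A or T before the other. The widest difference was 57.5 points, at the hexamer starting at position 198226 of chromosome 2, which had 86.8% on the plus strand after G and 29.3% on the minus strand after A or T.

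**Figure D3:**
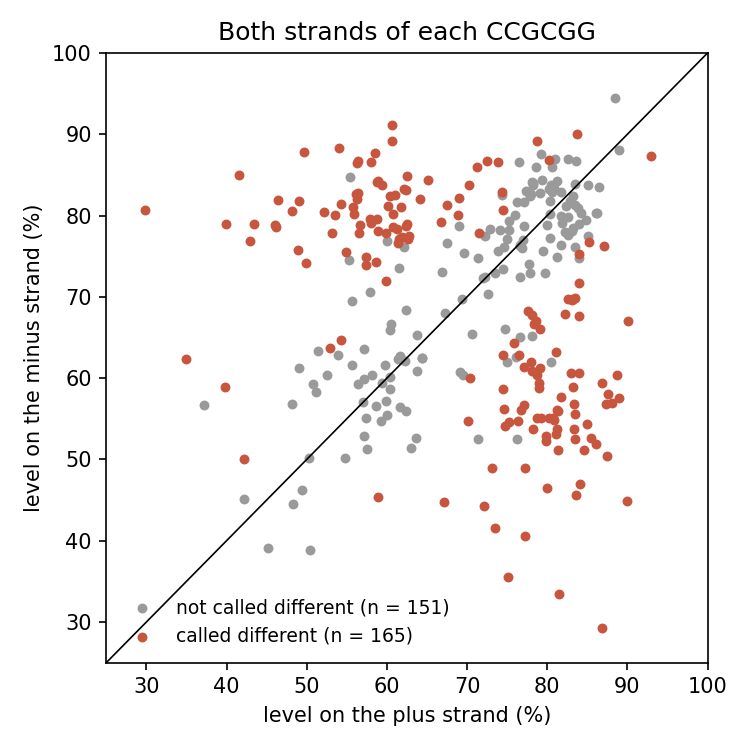
Level in percent on the plus strand (horizontal axis) and on the minus strand (vertical axis) at the second cytosine of each of 316 hexamers, mean of 3 libraries. The line marks equal levels. The 165 hexamers called different have a median distance of 21.7 percentage points between strands (5.70 to 57.5) and the 151 others one of 4.58 (up to 29.4). The ranges overlap.

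The genome consists of 2 chromosomes and 2 plasmids, and the level at the motif did not differ detectably between them. It was 69.8% ± 1.00 on chromosome 1 (486 sites), 70.7% ± 1.47 on chromosome 2 (72 sites), 70.1% ± 2.12 on plasmid pMP1 (73 sites) and 72.7% ± 2.16 on plasmid pSP1, where 2 of 8 sites were covered (SD, n = 3 libraries; adjusted p = 0.823 for each of the 6 pairs, permutation over sites, exact where a replicon had under 10 sites). The density of the hexamer, compared outside the plan, did differ. It was 9.74 per 100 kb on chromosome 1, 8.73 on chromosome 2, 22.0 on pMP1 and 8.67 on pSP1. The density on pMP1 was 2.26 times that on chromosome 1 (exact 95% confidence interval 1.57 to 3.17, exact binomial test, two-sided, adjusted p = 0.000112). The 337 copies were 0.074 times the 4549 expected from a first-order Markov model of the C, G and W sequence, with 0.068 on chromosome 1, 0.064 on chromosome 2, 0.239 on pMP1 and 0.222 on pSP1.

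Outside the hexamer, the residual level was 0.446% ± 0.155 after C, 0.545% ± 0.162 after G and 0.440% ± 0.149 after A or T (SD, n = 3 libraries). Most of these SDs came from the libraries' different backgrounds. Within libraries, the level after G was above that after C by 0.0985 ± 0.0081 percentage points and above that after A or T by 0.104 ± 0.0127 points (SD of the differences, n = 3 libraries), in 3 of 3 libraries each. An exact permutation test on 3 libraries cannot give a two-sided p under 0.25, so the differences are given as values.

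The libraries agreed closely at the motif. Across the 633 sites, which are not independent replicates, Pearson's r was 0.909 between libraries 1 and 2, 0.925 between 1 and 3 and 0.957 between 2 and 3, and the mean absolute difference was 3.99, 3.31 and 2.84 percentage points. Of 1899 comparisons of a site between libraries, 4 passed Fisher's exact test at an adjusted p of 0.05, all between libraries 1 and 3. The median range between libraries was 13.0 points at the 26 sites with under 50 reads in a library and 3.70 points at the others. The widest range was found at position 2536160 on the minus strand of chromosome 1, with 3.70%, 50% and 62.9% at 27, 16 and 35 reads. It was also among the 10 lowest motif sites, at a mean of 38.9% ± 31.1.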

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

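The alternatives without cytosines in inverted repeats, with a depth of at least 10% of the median and with the second-order Markov model were chosen after seeing the data. Of 80 alternatives over 14 results, 73 kept the direction and side of the threshold, or stayed within 1.5 times a count or 1 SD of a value, and 7 did not. The motif's level and shares are never negative, so for these only the side of the threshold could change. For 6 of the 73, values without a test with a library left out, this was fixed in advance, as the mean of 2 of 3 libraries cannot move by 1 SD; the same holds for 93 alternatives of the 31 named sites. Their other 31, on pooled reads, stayed within 1 SD, which such a weighted mean can hardly exceed. The high-level sites went from 604 to 929 at a level of at least 30% and to 344 at 70%. The intermediate sites went from 1987 to 5950 on pooled reads, to 3621 and 852 at a mean of at least 5% and 20%, and to 1010 without cytosines in inverted repeats; with a library left out they numbered 2035 to 2667. The hexamers with a strand difference went from 165 to 251 on pooled reads. Thresholds and pooling change these counts by construction, and the high-level sites can only rise in number where fewer libraries must pass. The other causes were not tested. The share of the motif among high-level sites passed its test in every alternative run but was not stable in size: it was 67.8% at 30%, 94.2% at 70%, 71.2% on pooled reads, 71.7% with 2 of 3 libraries and 76.2% to 90.9% with a library left out. The high-level sites outside the motif went from 46 to 175 without library 3, to 232 with 2 of 3 libraries and to 0 without cytosines in inverted repeats. The gene comparisons, with their coverage, library, level, upstream and Markov alternatives, were not run, for want of an annotation with matching coordinates. No paired analysis was possible because there is 1 group. Depth limits plasmid pSP1, where 2 of 8 motif cytosines were covered.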

Other observations

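In this part, the test of the deaminase's preference and that of the plasmid's GC content were written before their results; all other tests were chosen after the result was seen. The design has 1 group, so no biological explanation was tested except another methylated hexamer.

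CCGCGG was not the only rare palindrome of C and G. Among 8 such hexamers, CGGCCG had the lowest ratio to the first-order expectation, 0.047, followed by CCGCGG with 0.074, whereas GGCGCC stood at 0.886. The second base before CCGCGG was associated with the level too, accounting for 14.9% of the variance left by the first (adjusted permutation p = 0.00075). Mean levels ran from 49.0% ± 1.26 after CC to 83.4% ± 1.49 after GG (SD, n = 3 libraries). Taken alone, the second base accounted for 0.177% of the variance (adjusted permutation p = 0.607). The bases 4 and 5 places before the hexamer also passed after the first, with 3.28% and 2.97% of the variance left. Outside the motif, cytosines in perfect inverted repeats with at least 10 C:G pairs had a mean level of 9.37% and a median of 2.39%, and 23.7% of them were at a high or intermediate level. With at most 3 pairs, the mean was 0.541% and the median 0.391%.

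The level at the motif differed with its 5' base. Features of the surroundings that both strands share, such as GC content, are argued against. Within 78 hexamers with G before one strand and C before the other, the G strand was higher by 23.6 points on average (SD 9.85 over hexamers) and in 77 of 78. Each strand has its own reads and order of bases, so depth or composition of the single strand was not tested. A preference of the deaminase may contribute and cannot be told apart from a difference in methylation: at CCG outside the motif the smaller of the ratios of residual level, G against C and G against A or T, was 1.17 ± 0.0658 (SD, n = 3 libraries), between the bounds set for and against it. Residual level there was higher after C than after A or T, the opposite of the order at the motif. The deaminase's activity on N4-methylcytosine itself was not measured.

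Outside the motif, 1954 cytosines at high or intermediate level were grouped into clusters with a gap setting of 50 bp. Of the 293 clusters, 66 held a single site and 67 held at least 10 sites, with 1023 sites in the latter. Stem-loops that pair again during deamination are a candidate explanation for part of the 1954 sites. Of these sites, 51.8% lay in perfect inverted repeats with at least 6 C:G pairs against 5.11% of the others, a ratio of 10.1. Of the 941 sites left, 22.1% lay in repeats with 1 mismatch and at least 8 pairs against 1.82% of the others (50.6% and 20.4% with at least 6). Since W opposite W counted as a pair, these repeats may hold further mismatches between A or T bases. A hexamer methylated at its second base is argued against as the source of a large share of the sites, as the most frequent one, GCCGCC, held 2.46% of them. A methylated hexamer with few sites could not be seen by this share, and other places were not tested. Unconverted molecules were tested in 3 ways, the later 2 after the earlier outcomes were known.

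The first test counted thin coverage, under 10% of the median depth: 3.99% of the sites had it in every library and 13.8% in at least 1, against 1.66% and 3.12% of the others, which leaves it open for a minority of the sites. In the second, 93.9% of 66 clusters of at least 5 sites without a perfect stem of 6 C:G pairs lay on 1 strand (66.0% of 97 with one), as single molecules would give. In the third, 70.1% of the cytosines passing in library 3 also passed in both others, above the bound of 50% set against random escape, with 50.9% for library 2 and 34.1% for library 1. Without perfect stems the shares were 61.7%, 36.7% and 19.8% for libraries 3, 2 and 1. The bound was set for library 3 only. The same 1512 cytosines recurred in all 3 libraries, so the first shares differ only by how many cytosines passed in each library. Passing independently, at an equal rate at all cytosines, would give at most 0.000295%. Escape of that kind is argued against for the recurring sites as a set, and is left open for the cytosines that did not recur. What keeps the clusters on 1 strand unconverted stays open. The largest of them, 30 sites on plasmid pMP1 at 61.2%, 78.9% and 34.0% in the 3 libraries, is itself thinly covered, with median depths of 31.5, 18 and 14 reads against 373, 269 and 708 over all cytosines.

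Plasmid pSP1 had 1.97% ± 0.494 of the median depth of chromosome 1 (SD, n = 3 libraries), against 50.4% for pMP1 and 83.1% for chromosome 2. Depth rose with GC content across 500 bp windows of chromosome 1 (Spearman's rho 0.905, 0.905 and 0.907), and pSP1 has 56.2% GC against 67.1%. Against chromosome 1 windows of equal GC content, the depth ratio of pSP1 was 0.387 ± 0.0489 over the 73 of its 92 windows that could be matched. The others were left out, so this ratio and the 1.97% do not cover the same windows. Matched in the same way, pMP1 stood at 0.964, 0.937 and 0.935 in libraries 1, 2 and 3, and chromosome 2 at 0.836, 0.829 and 0.827. GC content may thus account for part of the deficit of pSP1 in the matched windows, but the ratio of pSP1 lies between the bounds of 0.5 and 0.25 set before. Copy number and mapping were not tested, so the cause cannot be told apart.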
